A study of Caenorhabditis elegans with 6 samples.

How the data were processed

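RNA had been extracted from whole infected animals and sequenced from 6 libraries, 3 per group, per the labels' protocols. The authors deposited whole-number read counts per gene, not normalized, in 1 file per library. The submitters' processing notes name HTSeq and DESeq2 without versions. The aligner, genome build, annotation and strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as those of the *hsp-16* and major sperm protein families, cannot be told apart with certainty. Samples were grouped by their titles, which also number the replicates.

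Each file held 45461 gene entries under sequence names, of which 44936 matched the Ensembl release 115 annotation of WBcel235. The other 525 took 0.249% to 0.386% of a library's counts. Coordinates and gene types are those of that annotation, which may not be the one the authors used. Symbols shared by 2 entries, and list symbols without a match, were then looked up in RefSeq names, a step added after the counts had been seen; 21 list symbols stayed unmatched. No entry stood for reads without a gene. 23121 entries were 0 in every library, as were all 14 mitochondrial entries, so mitochondrial transcripts are not analysed here. Totals ran from 16352730 to 21421213 counts, so that 3 counts, the limit a count of 0 allows, correspond to 0.14 to 0.183 CPM (counts scaled to library size) in 1 library. Intervals for summed counts are exact binomial 95% intervals and cover counting error only.

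Counts were tested with edgeR 4.0.16 in R 4.3.3: default expression filter, TMM scaling, robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are mutant-labelled over control-labelled. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD. The filter kept 13088 genes with 99.85% of all counts. Counts of different libraries of a group differed by more than sampling noise, with chi-square per degree of freedom of 7.84 to 219, so each was counted as 1 sample.

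Before the data were examined, 58 gene lists, the rule for named genes and the alternatives were fixed. The lists were p38 PMK-1 targets, ZIP-2 pathway, C-type lectins, lysozymes, saposin-like and defensin-like genes, epidermal antimicrobial peptides, intracellular pathogen response, CUB-like genes, DAF-16 targets, insulin-like peptides, heat shock, endoplasmic reticulum and mitochondrial unfolded protein responses, SKN-1 targets, glutathione transferases, UDP-glucuronosyltransferases, cytochrome P450, hypoxia, osmotic stress, fatty acid desaturation and elongation, fatty acid oxidation and lipolysis, autophagy, lysosomal and digestive proteases, collagens, chemoreceptors, srbc receptors, AWC neurons, neuropeptides, guanylyl cyclases, globins and oxygen sensing, nuclear hormone receptors, F-box genes, MATH and BATH genes, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, ribosomal RNA, oxidative phosphorylation, proteasome, galectins, thaumatins, transthyretin-like and lipocalin genes, ABC transporters, metallothionein and cadmium response, the TGF-beta pathway, G protein coupled immune regulators, vitellogenins, sperm, oocyte and eggshell, germline, embryonic zygotic genes, and markers of intestine, body wall muscle, pharynx, epidermis, neurons, uterus with spermatheca and vulva, and coelomocytes with excretory cells. Lists with at least 5 measured members, 54 in all, were tested with camera (limma 3.58.1; preset correlation 0.01). The srbc, ribosomal RNA and thaumatin lists were too small, and no symbol of the mitochondrially encoded list matched.

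Named genes were *srbc-48* and *fer-1*; the 15 largest rises and 15 largest falls among protein-coding genes that passed, averaged at least 5 CPM and had all mutant-labelled libraries on 1 side of all control-labelled libraries; and up to 4 members of each list with the smallest p. *unc-86*, C30A5.11, the neighbours of both loci, and list members outside that rule were named after their values were seen.

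On simulated counts for 12895 genes with the spread of these libraries, 100 genes were changed 2-fold and 100 genes 4-fold. The test recovered 5% of the former and 50% of the latter, with 4 false calls. With so few genes changed, the adjusted p threshold was stricter than in the real comparison with 8135 calls. These shares therefore do not measure recovery there. The alternatives were DESeq2 1.42.0, voom with sample quality weights, RLE, upper quartile and no scaling factors, no filter, a mean of at least 5 CPM, adjusted p under 0.01, a test against a 1.5-fold change, a replicate block, leaving out each library in turn, and for lists an estimated correlation and fry. Gene lists for tests of the collagen pattern were written after it had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.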

Results

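Gene counts were analysed from whole *Caenorhabditis elegans* collected after 24 h on the pathogenic bacterium *Pseudomonas aeruginosa* PA14 at 25 °C. The animals had been grown to young adults at 20 °C. The labels give 3 control libraries, with the genotype *kyIs262;fer-1*, and 3 libraries of a mutant in *srbc-48*, a gene of the srbc family of chemoreceptors, in a *fer-1* background. *fer-1* is a gene needed for sperm function. The single comparison asks how infected mutant animals differed from infected control animals. By the labels the groups also differ in *kyIs262*, so no difference can be assigned to *srbc-48* alone. No library came from uninfected animals, so a changed response to infection cannot be told from a difference present without it. Libraries held 16352730, 19361285 and 17926952 counts in control replicates 1, 2 and 3, and 17645597, 21421213 and 19341499 in mutant replicates 1, 2 and 3. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

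No read was counted for *srbc-48* (sequence name F54B8.6, chromosome V, 15820283 to 15821383 in WBcel235) in any of the 6 libraries. A count of 0 allows a level of up to 0.0559 CPM (counts scaled to library size) in the pooled control libraries and 0.0514 in the pooled mutant libraries. The gene therefore gives no check of the labels. *fer-1* (chromosome I, 8623012 to 8631202) had 9, 8 and 5 counts in the control libraries and 5, 16 and 4 in the mutant libraries, and was too low to test.

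Reads at *odr-1* and *unc-86* were higher in the libraries labelled mutant, which goes against the genotype labels if *kyIs262* holds sequences of both genes. These reads do not settle the labels, since developing progeny was not tested as their source. For *unc-86* a larger share of neurons was not excluded. By general knowledge, *kyIs262* is an integrated transgene in which regulatory sequences of *unc-86*, a neuronal transcription factor, and *odr-1*, a guanylyl cyclase of AWC neurons, drive fluorescent reporters; the labels name it for the control only. *odr-1* (chromosome X, 13544729 to 13550990) had 1, 5 and 1 counts in the libraries labelled control and 294, 591 and 240 in those labelled mutant. The next gene upstream, *glb-20*, a globin (chromosome X, 13552339 to 13556166), had 18, 36 and 20 against 5382, 15481 and 6433 counts. *unc-86* (chromosome III, 8212740 to 8216336) had 3, 6 and 10 against 84, 437 and 107 counts. C30A5.11, a noncoding RNA gene upstream of it (chromosome III, 8216458 to 8216570), had no count in the control-labelled libraries and 124, 152 and 145 in the others, at least 149-fold higher with 3 counts allowed over the control group. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00117 for *odr-1*, 0.000515 for *glb-20*, 0.00405 for *unc-86* and 0.00152 for C30A5.11. The summed counts of *unc-86* gave a ratio of 35.1 (95% counting interval 22.3 to 58.7), and its log2 fold change was 4.19 without mutant replicate 2. Of the other genes near the loci, *cah-4* was called higher (log2 fold change 1.16, edgeR adjusted p = 0.0347), *mob-4* and C50C3.1 lower (-1.28 and -1.21, adjusted p = 0.00522 and 0.0372), and R01E6.7 did not pass (-0.79, adjusted p = 0.196). R01E6.2 (chromosome X, 13565486 to 13566536) and C30A5.10 (chromosome III, 8205124 to 8209875) had no count in the control-labelled libraries and 24, 45 and 4, and 25, 85 and 8, in the others, and were too low to test. *unc-86*, C30A5.11 and these neighbours were singled out after their values were seen. Groups were kept as labelled, and every direction given here is that of libraries labelled mutant relative to libraries labelled control.

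**Figure D1:**
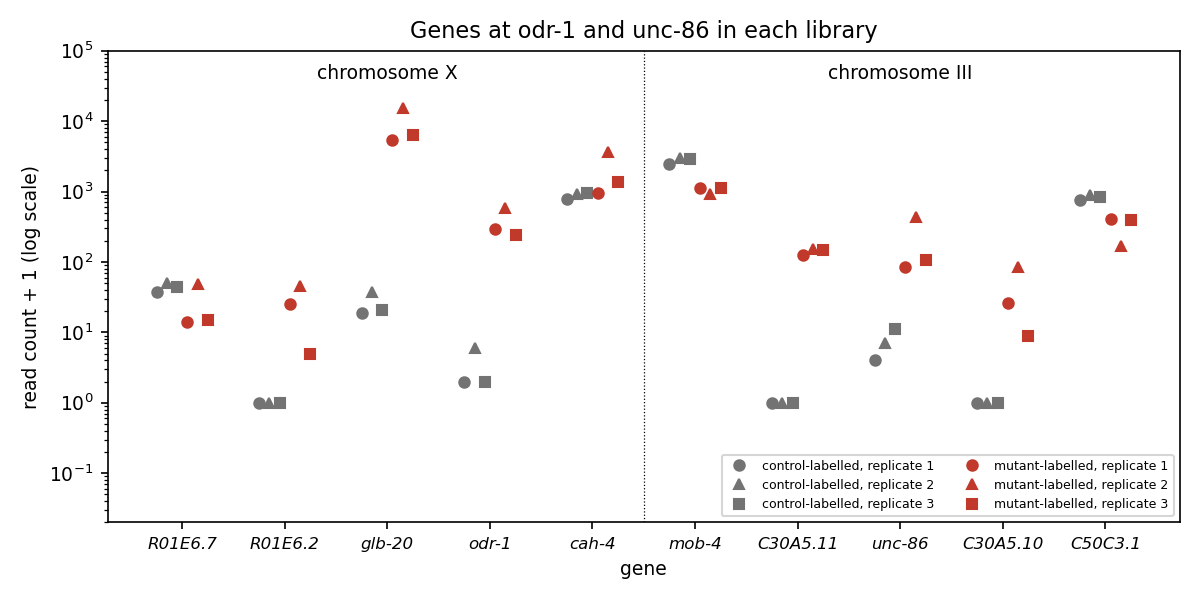
Read counts plus 1 (log axis) of genes at *odr-1* on chromosome X and at *unc-86* on chromosome III, 1 point per library, with grey for control-labelled, red for mutant-labelled and shapes for replicates 1 to 3. *glb-20* had at most 36 counts in a control-labelled library and at least 5382 in a mutant-labelled library, while the neighbouring gene *cah-4*, also called higher, had 784 to 948 against 945 to 3628.

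In mutant-labelled animals 75 of 106 measured collagens rose, as did 15 of 18 epidermis markers, 14 of 19 body wall muscle markers, 16 of 22 pan-neuronal markers and 16 of 19 intestine markers. Of 29 germline genes 19 fell and none rose, and of 225 F-box genes 108 fell and 47 rose. These lists were called by camera, a test of gene lists, with its preset correlation, but it called none of 54 lists with an estimated correlation (smallest adjusted p = 0.536). Of the 15 largest rises 10 were collagens, among them *sqt-1* and *dpy-13*, and the 15 largest falls included *tbx-38* and *pes-10*. Of 13088 genes tested with the edgeR quasi-likelihood test, 4383 were higher and 3752 lower. Changes of at least 2-fold were estimated for 4013 of the former and 2154 of the latter. With 62.2% of all tested genes called, the counts of any list are to be read against these totals.

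Rises made up 53.9% of the calls, but 70.8% with upper quartile scaling and 41.8% with library sizes only. The median log2 fold change of all tested genes was 0.18, and 0.51 and -0.02 with those scalings, so small changes are relative to the scaling. Mutant replicate 2 lay apart from the rest, with correlations of 0.686, 0.681 and 0.696 to the 3 control libraries across genes, against 0.857 to 0.891 for the other mutant libraries. Without it 4543 genes were higher and 4268 lower. Leaving out control replicate 1, 2 or 3 left 3743, 4033 or 4011 calls in place of 8135, and leaving out mutant replicate 1 left 2405 genes lower.

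**Figure D2:**
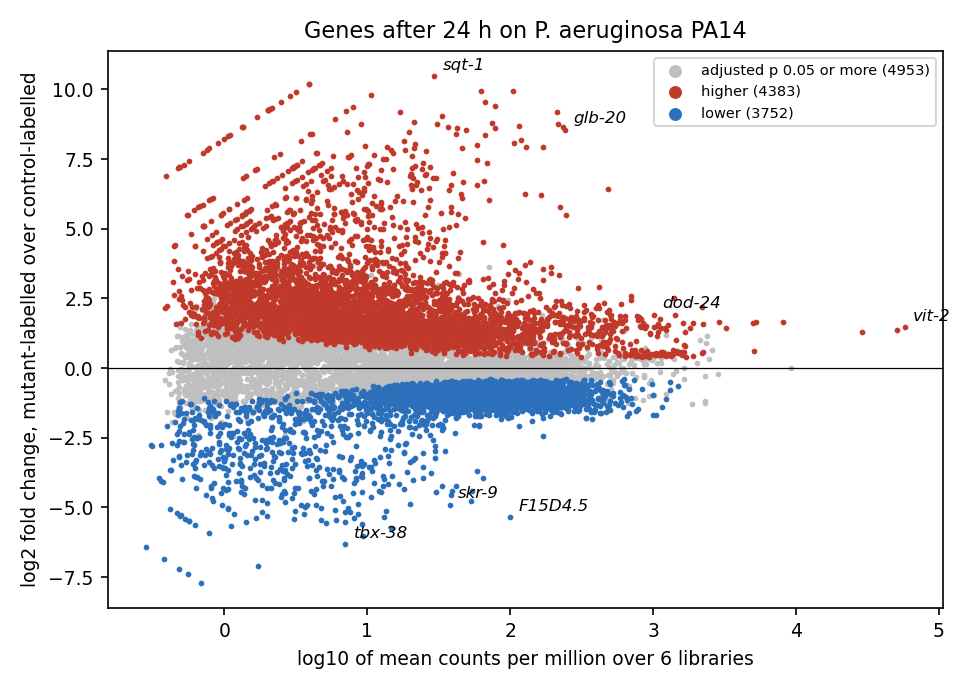
Each point is 1 of 13088 tested genes, placed by the log10 of its mean CPM over 6 libraries and its log2 fold change, mutant-labelled over control-labelled. Red points are the 4383 genes that passed the edgeR test as higher, blue points the 3752 that passed as lower, and grey points the rest.

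Among the 15 largest rises, 10 were collagen genes: *sqt-1*, *col-147*, *dpy-13*, *col-167*, *col-17*, *col-168*, *col-107*, *col-117*, *rol-8* and *col-39*. *dpy-13* (chromosome IV, 4235614 to 4236710), whose loss shortens the body, rose from 0.122 ± 0.0306 to 124 ± 190 CPM (SD, n = 3), a log2 fold change of 9.93 ± 1.92 (SE). *col-107* (chromosome IV, 1548721 to 1549714) rose from 0.709 ± 0.42 to 428 ± 658 CPM. *sqt-1* (chromosome II, 11336693 to 11337837) had 2 control counts and 3693 mutant counts in all, a ratio of 1960 with a 95% counting interval of 542 to 16200. Ratios over 1 to 3 control counts were 1320 (236 to 52100) for *grl-5*, a hedgehog-related gene, 1040 (187 to 41300) for *col-168* and 757 (259 to 3670) for *col-117*. They were 873 (156 to 34500) for ZK154.1, 785 (140 to 31000) for K02E11.10 and 575 (159 to 4750) for the peroxidase gene *skpo-2*. C08E3.13 completed the 15. These intervals cover counting error only.

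The size of these rises came in part from mutant replicate 2. Without it the log2 fold changes of the 15 were 4.29 to 8.96 in place of 8.77 to 10.47. The value was 7.46 for *sqt-1* in place of 10.47, 6.92 for *dpy-13* in place of 9.93, 5.03 for *col-147* in place of 9.94 and 6.12 for *col-107* in place of 9.20. All 15 passed the edgeR test in both fits, with adjusted p up to 0.0164 over all libraries. DESeq2 gave no adjusted p for several of them, so it did not call these. They included *sqt-1*, *col-147*, *col-167*, *col-17*, *col-168*, *col-107* and *col-117*. Low level alone does not account for this. *col-107*, at 428 CPM in the mutant-labelled libraries, had no adjusted p, while ZK154.1, at 14.1 CPM, had one. Voom gave mutant replicate 2 a quality weight of 0.068, against 0.843 to 3.579 for the other libraries. The calls of *col-147*, C08E3.13 and *col-39* were lost when any 1 control library was left out, with adjusted p = 0.0504 to 0.0645 by edgeR, and that of *col-168* without control replicate 2 (0.0514). With no filter on low counts edgeR gave adjusted p = 0.0757 for *col-147*, 0.0548 for *col-117*, 0.0771 for C08E3.13 and 0.0644 for *col-39*.

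The 15 largest falls included *tbx-38* and *tbx-37*, T-box factors of the early embryo, and *pes-10*, an early embryonic transcript. *tbx-38* (chromosome III, 11784082 to 11786061) fell from 13.9 ± 3.97 to 0.169 ± 0.0699 CPM (SD, n = 3), a log2 fold change of -6.32 ± 0.48 (SE; edgeR adjusted p = 0.000809). *pes-10* (chromosome II, 12846191 to 12847836) fell by 5.58 on the log2 scale. *pap-2* fell by 5.73, and *pap-3* also fell. *skr-9*, a Skp1-related gene, fell by 4.90 on the log2 scale. *fbxb-119*, an F-box gene, fell from 13.6 ± 1.15 to 0.372 ± 0.195, and *bath-31* fell by 5.09 on the log2 scale. F15D4.5 was the most abundant of the 15, at 196 ± 4.24 against 4.78 ± 1.39 CPM. Y5H2B.3, F38C2.7, Y116A8C.19, F15D4.6, R02C2.1 and EEED8.4 made up the rest. Without mutant replicate 2 the log2 fold changes of the 15 were -4.84 to -6.13. Several belong to gene families, and how far the authors' counting divided reads between similar copies was not tested.

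Collagens rose as a group. Of 106 measured collagens 75 rose and 1 fell (76 and 1 adjusted over the list alone), with a median log2 fold change of 5.57; the median was the same when 12 genes with few counts were held at their bound, and was 3.19 without mutant replicate 2. *dpy-17*, *dpy-14* and *sqt-3* rose by 5.79 ± 0.40, 6.23 ± 0.44 and 6.44 ± 0.46 (log2, SE). Camera, which compares a list with all other genes, gave adjusted p = 1.79e-09 with a preset correlation and adjusted p = 0.672 with an estimated correlation. Of 18 epidermis markers 15 rose and 1 fell (the same adjusted over the list alone), with *dpy-7* up by 6.40 ± 0.51 and the hedgehog-related *wrt-2* by 7.83 ± 0.84 (camera adjusted p = 0.000362, and adjusted p = 0.672 with an estimated correlation). Body wall muscle markers rose in 14 of 19 cases and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 9.54e-05, and adjusted p = 0.672 with an estimated correlation). Without mutant replicate 2 the epidermis median was 1.65 in place of 2.73. Troponin T *tnt-2* rose from 85.7 ± 19.6 to 406 ± 78.3 CPM and *unc-87*, a thin filament protein, from 115 ± 14.5 to 473 ± 112 (SD, n = 3).

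Neuronal genes also rose. Of 22 pan-neuronal markers 16 rose and none fell (18 and 0 adjusted over the list alone), with *unc-64*, syntaxin, up by 1.70 ± 0.28 and *tbb-4*, a tubulin of ciliated neurons, by 3.56 ± 0.63 (log2, SE; camera adjusted p = 0.0025, and adjusted p = 0.674 with an estimated correlation). Neuropeptide genes rose in 61 of 78 cases, and in 63 adjusted over the list alone, with none lower (camera adjusted p = 3.32e-07, and adjusted p = 0.674 with an estimated correlation); *flp-6* rose by 2.61 ± 0.26 and *nlp-40*, an intestinal peptide, by 1.48 ± 0.16. Of 10 AWC neuron genes 8 rose and none fell, the same adjusted over the list alone, among them *nsy-4* (3.90 ± 0.49), *ceh-36* (4.04 ± 0.74) and *odr-1* itself (camera adjusted p = 0.00754, and adjusted p = 0.672 with an estimated correlation). Globins and oxygen-sensing genes rose in 11 of 15 cases with none lower, the same adjusted over the list alone, led by *glb-20*, the gene next to *odr-1* (camera adjusted p = 0.00225, and adjusted p = 0.674 with an estimated correlation). Guanylyl cyclases (6 of 13 higher, none lower, and adjusted p = 0.142) and chemoreceptors (9 higher and 6 lower of 36, or 9 and 5 adjusted over the list alone, with adjusted p = 0.676) were not called as lists by camera. Without mutant replicate 2 the medians were 1.298 in place of 2.51 for pan-neuronal markers, 1.29 in place of 2.38 for neuropeptides, 1.58 in place of 3.16 for AWC genes and 0.42 in place of 1.70 for guanylyl cyclases. None of the 69 srbc receptor genes was high enough to test.

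Markers of other tissues were mixed. Coelomocyte and excretory markers rose in 9 of 13 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0498, and adjusted p = 0.672 with an estimated correlation), led by *ceh-34*, up by 3.64 ± 0.41 (log2, SE). That list lost its call without control replicate 1 (camera adjusted p = 0.0687), control replicate 3 (0.0554) or mutant replicate 3 (0.0725). Pharynx markers (9 of 17 higher, none lower, camera adjusted p = 0.0691) and uterus, spermatheca and vulva markers (8 higher and 3 lower of 18, adjusted p = 0.516) were not called. The pharynx median was 1.104 in place of 1.71 without mutant replicate 2. The pharynx list was called without control replicate 3 (0.0474) or mutant replicate 3 (0.0057).

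Germline genes were lower. Of 29 germline genes 19 fell and none rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -1.08 (camera adjusted p = 5.32e-06, and adjusted p = 0.674 with an estimated correlation). *mes-3*, a chromatin regulator of the germline, fell from 128 ± 6.38 to 62.7 ± 7.04 CPM (SD, n = 3), and *syp-1*, of the synaptonemal complex, from 55.5 ± 2.41 to 17.7 ± 5.69. Oocyte and eggshell genes fell in 10 of 24 cases with none higher, the same adjusted over the list alone, including *mbk-2* and *lin-41* (camera adjusted p = 9.89e-05, and adjusted p = 0.674 with an estimated correlation). Without mutant replicate 2, 26 germline genes and 21 oocyte and eggshell genes were lower and 1 of the latter higher, while the medians were -0.67 in place of -1.08 and -0.71 in place of -1.21. Sperm genes were not called as a list (4 higher, 2 lower of 16, or 4 and 1 adjusted over the list alone, camera adjusted p = 0.835), nor were replication-dependent histones (5 higher, 3 lower of 26, or 4 and 2 adjusted over the list alone, adjusted p = 0.721). Of these histones 6 were higher and 6 lower without mutant replicate 2.

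Embryonic zygotic genes went both ways, with 11 lower and 9 higher of 23, the same adjusted over the list alone (camera adjusted p = 0.0498, lower, and adjusted p = 0.672 with an estimated correlation). *vet-1* and *vet-2*, transcribed very early in the embryo, fell from 63.5 ± 8.38 to 3.33 ± 0.511 and from 121 ± 18.6 to 7.83 ± 1.96 CPM (SD, n = 3), together with *pes-10*, *tbx-37* and *tbx-38*. The 9 that rose included *pha-4*, by 2.57, and *ceh-22*, which is also among the pharynx markers, by 4.24 (log2). The median of the 23 was -1.196, and -0.79 without mutant replicate 2. Yolk protein genes took 8.49% to 8.66% of all counts in the control-labelled libraries and 19.2%, 14.4% and 23.3% in mutant-labelled replicates 1, 2 and 3. Of 6 vitellogenin genes 3 rose, the same adjusted over the list alone: *vit-2* by 1.48 ± 0.22, *vit-6* by 1.37 ± 0.23 and *vit-5* by 1.29 ± 0.22 (camera adjusted p = 0.0362, and adjusted p = 0.674 with an estimated correlation). All 6 passed without mutant replicate 2, while the list was not called without control replicate 1 (camera adjusted p = 0.0572), control replicate 3 (0.0775), mutant replicate 1 (0.0932) or mutant replicate 3 (0.175).

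**Figure D3:**
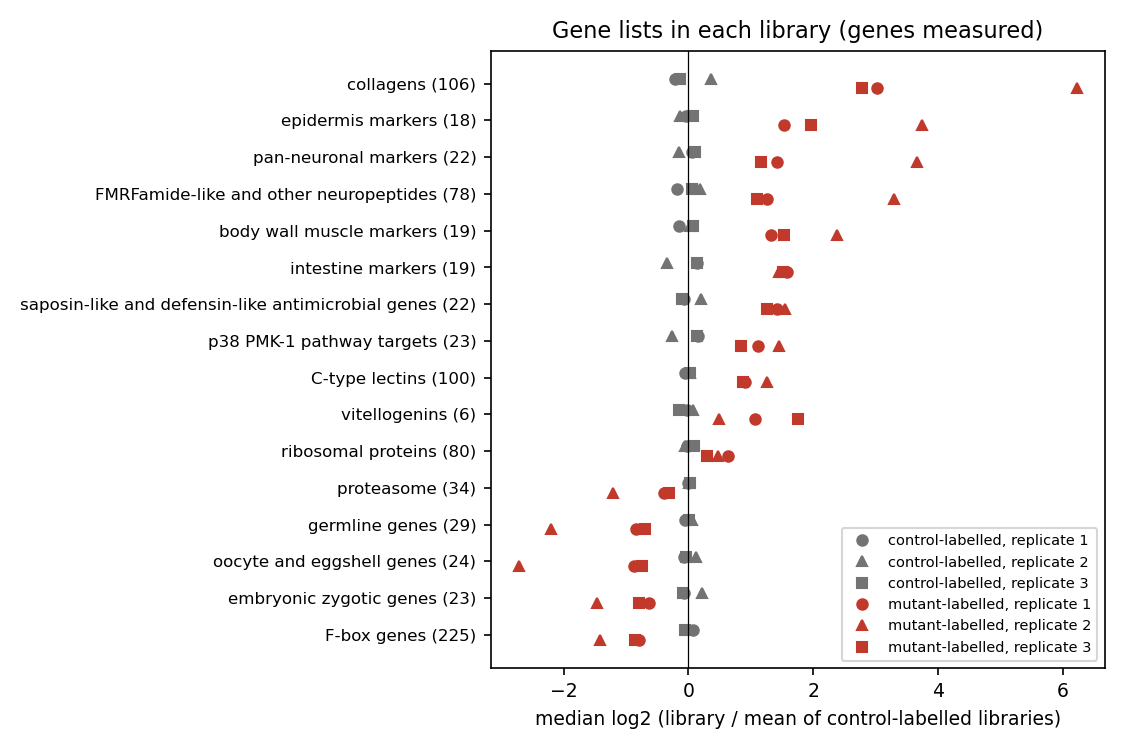
Points show, for each library, the median over a gene list of the log2 level relative to the mean of the control-labelled libraries, with the number of measured genes in parentheses. Grey points are control-labelled and red points mutant-labelled libraries, with shapes for replicates 1 to 3; collagens lay at 3.03, 6.23 and 2.78 in mutant-labelled replicates 1, 2 and 3.

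Several lists of immune effectors were called higher, in the same libraries in which intestine markers rose. Of 23 targets and components of the p38 kinase PMK-1, an antibacterial pathway of the intestine, 11 rose and none fell, the same adjusted over the list alone (median log2 fold change 1.18; camera adjusted p = 0.00462, and adjusted p = 0.672 with an estimated correlation). *dod-24* rose from 422 ± 112 to 1598 ± 546 CPM (SD, n = 3) and the lectin *clec-85* from 177 ± 40.2 to 550 ± 185. The kinase genes *pmk-1*, *sek-1* and *nsy-1* had log2 fold changes of 0.49, 0.63 and 0.33 (edgeR adjusted p = 0.179, 0.068 and 0.362), and *sek-1* passed without mutant replicate 2 (0.0418) or 3 (0.0263), with upper quartile scaling (0.0266), with a mean of at least 5 CPM (0.0439) and by voom with quality weights (0.047). CUB-like domain genes rose in 10 of 18 cases with none lower, the same adjusted over the list alone (camera adjusted p = 0.00313, and adjusted p = 0.672 with an estimated correlation), and F55G11.8 by 1.67 ± 0.28 (log2, SE). Of 100 C-type lectins 44 rose and 7 fell (41 and 6 adjusted over the list alone), with *clec-62* up by 1.67 ± 0.16 and *clec-56* by 1.81 ± 0.18 (camera adjusted p = 0.00182, and adjusted p = 0.62 with an estimated correlation). Saposin-like and defensin-like genes rose in 18 of 22 cases with none lower, the same adjusted over the list alone (camera adjusted p = 1.72e-05, and adjusted p = 0.536 with an estimated correlation); *spp-5* rose from 697 ± 90.6 to 1776 ± 150. Intestine markers rose in 16 of 19 cases with none lower, the same adjusted over the list alone, by a median of 1.52 (camera adjusted p = 5.32e-06, and adjusted p = 0.536 with an estimated correlation), including the proton pump gene *vha-6*, from 296 ± 23.9 to 909 ± 77.6.

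Intracellular pathogen response genes rose in 12 of 21 cases with none lower (11 adjusted over the list alone; camera adjusted p = 0.00733, and adjusted p = 0.672 with an estimated correlation), with *skr-3* up by 1.74 ± 0.31 and *pals-24* by 1.32 ± 0.30 (log2, SE). Galectins rose in 10 of 12 cases with none lower, the same adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.536 with an estimated correlation). Of 12 genes of the ZIP-2 pathway and early infection response, *zip-2*, *irg-2*, *irg-3* and F11D11.3 rose and *cebp-2* fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.145), with *zip-2* from 165 ± 39.8 to 422 ± 57.5 CPM (SD, n = 3). Of 11 lysozymes, *lys-8*, *lys-4*, *lys-1* and *ilys-4* rose and *lys-7* fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.122). Without control replicate 3, edgeR gave adjusted p = 0.057 for *irg-2*, 0.0768 for *irg-3*, 0.0643 for F11D11.3, 0.0582 for *lys-4*, 0.0555 for *lys-1*, 0.0936 for *ilys-4*, 0.125 for *lys-7* and 0.0837 for *cebp-2*. Without control replicate 2 it gave 0.0515, 0.0736, 0.0668, 0.0581 and 0.0929 for *irg-2*, *irg-3*, F11D11.3, *lys-1* and *ilys-4*, and 0.0681 and 0.118 for *lys-7* and *cebp-2*. Calls were also lost without control replicate 1 (*lys-4* 0.0662, *ilys-4* 0.0644, *lys-7* 0.0716, *cebp-2* 0.114), mutant replicate 1 (*irg-3* 0.0584, *ilys-4* 0.0521, *cebp-2* 0.124), mutant replicate 2 (*ilys-4* 0.0501, *lys-7* 0.106) and mutant replicate 3 (*lys-7* 0.0786). Library sizes only gave 0.0704 for *ilys-4*, upper quartile scaling 0.153 for *lys-7* and 0.15 for *cebp-2*, RLE scaling 0.0594 for *cebp-2*, and a mean of at least 5 CPM 0.101 for *lys-7* and 0.0648 for *cebp-2*. Epidermal antimicrobial peptides (3 higher, 1 lower of 24; 0 and 0 adjusted over the list alone; camera adjusted p = 0.214) were not called, except without control replicate 2 (0.00314) among the fits that left out a library, and their median of 1.099 was 0.34 without mutant replicate 2 and 2.58 without control replicate 2. G protein coupled immune regulators (9 higher, 2 lower of 17, and adjusted p = 0.167) were not called by camera, and neither of 2 measured thaumatins passed.

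Lists of lipid and xenobiotic metabolism were called higher. Over all tested genes 4383 of 13088 were higher, and counts here such as 14 of 36, 19 of 47 and 19 of 50 lie near that share. Fatty acid desaturation and elongation genes rose in 11 of 19 cases with none lower (10 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.672 with an estimated correlation), including the desaturase gene *fat-6*, up by 1.29 ± 0.22, and the fatty acid synthase gene *fasn-1*, up by 1.82 ± 0.39 (log2, SE). Fatty acid oxidation and lipolysis genes rose in 14 of 36 cases and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.672 with an estimated correlation), with the lipid-binding protein gene *lbp-2* up by 1.73 ± 0.17. Glutathione transferases rose in 16 of 28 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.672 with an estimated correlation), UDP-glucuronosyltransferases in 19 of 47 with 1 lower (13 and 0 adjusted over the list alone; camera adjusted p = 0.00366, and adjusted p = 0.62 with an estimated correlation). Cytochrome P450 genes rose in 19 of 50 cases and fell in 4 (16 and 2 adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.674 with an estimated correlation), led by *cyp-13A5*, up by 2.25 ± 0.26. Lysosomal and digestive proteases rose in 14 of 22 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 5.74e-05, and adjusted p = 0.536 with an estimated correlation); *asp-1* rose from 3881 ± 155 to 12270 ± 1237 CPM (SD, n = 3). In the same libraries intestine markers were higher by a median of 1.52.

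Some of these list calls depended on single libraries. The P450 list was not called without control replicate 1 (camera adjusted p = 0.0572), control replicate 3 (0.0965), mutant replicate 2 (0.148) or mutant replicate 3 (0.0831). Fatty acid desaturation and elongation lost its call without control replicate 1 (0.0639), mutant replicate 1 (0.0652) or mutant replicate 3 (0.0716), and fatty acid oxidation and lipolysis without control replicate 1 (0.0687), control replicate 3 (0.0775), mutant replicate 1 (0.0588) or mutant replicate 3 (0.171).

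Stress response lists were not called by camera over all libraries. Mitochondrial unfolded protein response genes fell in 6 of 12 cases, with *hsp-6*, a mitochondrial chaperone, at a log2 fold change of -0.82 ± 0.14 (SE), and 1, *dve-1*, rose, a call lost without control replicate 1 (edgeR adjusted p = 0.0521), 2 (0.0634) or 3 (0.0533). The list was not called (camera adjusted p = 0.0614), but was without control replicate 2 (0.0434). Unfolded protein response genes of the endoplasmic reticulum rose in 9 and fell in 6 of 25 cases (adjusted p = 0.416), with *abu-14* up by 5.78 ± 0.65 (log2, SE; 5.01 without mutant replicate 2). The heat shock list (1 higher, 2 lower of 11, and adjusted p = 0.504) held *hsf-1*, the heat shock transcription factor, which fell by 1.19 on the log2 scale; its median of -0.29 and the test pointed down while its mean was 0.28, and the median was 0.02 with upper quartile scaling and 0.08 without mutant replicate 2. DAF-16 targets (7 higher, 2 lower of 23, or 6 and 1 adjusted over the list alone, adjusted p = 0.142), SKN-1 targets (6 higher, 2 lower of 17; 0.756), hypoxia genes (4 higher, none lower of 14; 0.147) and metallothionein and cadmium response genes (7 higher, none lower of 11; 0.0578) were not called by camera, although the last list was without control replicate 2 (0.0445). Of the SKN-1 targets 5 were higher and 4 lower without mutant replicate 2. Osmotic stress genes (3 higher, none lower of 9; 0.0812) were called without control replicate 2 (0.00638) or mutant replicate 1 (0.0362), and their median of 1.02 was 0.41 without mutant replicate 2, 2.41 without control replicate 2, and 0.52 and 0.58 without control replicates 1 and 3. Autophagy genes (4 higher, 2 lower of 18, or 4 and 1 adjusted over the list alone, 0.746), with *sqst-1* up by 1.72 ± 0.20, and nuclear-encoded oxidative phosphorylation genes (3 higher, 2 lower of 35, or 1 and 0 adjusted over the list alone, 0.966; 8 and 3 without mutant replicate 2) had medians near 0 whose sign, like that of the SKN-1 targets, changed between scalings.

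Proteasome genes fell in 11 of 34 cases with none higher (1 adjusted over the list alone; camera adjusted p = 0.00034, and adjusted p = 0.674 with an estimated correlation). Over all tested genes 3752 of 13088 were lower, a share near that of this list. Without mutant replicate 2, 21 proteasome genes were lower and their median was -0.28 in place of -0.61. The leading member, *skn-1*, is a transcription factor rather than a subunit, and fell by 0.73 on the log2 scale; the subunit gene *rpn-6.1* fell by 0.88, a call lost without control replicate 2 (edgeR adjusted p = 0.058) or 3 (0.0511). Ribosomal protein genes rose in 55 of 80 cases and fell in 1, the same adjusted over the list alone, by a median of 0.47 (camera adjusted p = 0.00034, and 0.0501 without mutant replicate 1, and adjusted p = 0.674 with an estimated correlation). *rpl-25.1* and *rpl-11.2* rose by 1.71 ± 0.22 and 1.89 ± 0.31 (log2, SE). F-box genes fell in 108 and rose in 47 of 225 cases (110 and 51 adjusted over the list alone; camera adjusted p = 6.04e-05, and adjusted p = 0.536 with an estimated correlation), with *fbxb-84* from 12.9 ± 3.22 to 0.809 ± 0.147 CPM (SD, n = 3). MATH and BATH domain genes (13 higher, 16 lower of 50, and adjusted p = 0.17) were not called by camera. Of 167 nuclear hormone receptors 91 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 1.35e-05, and adjusted p = 0.674 with an estimated correlation); the leading member, *nhr-2*, an early embryonic receptor, fell by 3.21 on the log2 scale.

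Transthyretin-like and lipocalin genes rose in 35 of 46 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 1.65e-07, and adjusted p = 0.62 with an estimated correlation), with *ttr-2* from 147 ± 26.4 to 654 ± 70.4 CPM (SD, n = 3). The TGF-beta and body size list rose in 9 of 17 cases with none lower, the same adjusted over the list alone (camera adjusted p = 0.0365, and adjusted p = 0.674 with an estimated correlation), led by *lon-1*, which limits body length, up by 2.06 ± 0.38 (log2, SE). That list was not called without control replicate 1 (camera adjusted p = 0.0554), control replicate 3 (0.0554) or mutant replicate 2 (0.198). In the last of these fits 10 of its genes were higher and 2 lower. Insulin-like peptides (5 higher, 1 lower of 15, or 3 and 0 adjusted over the list alone, adjusted p = 0.214) and ABC transporters (13 higher, 7 lower of 38, or 11 and 7 adjusted over the list alone, 0.407) were not called by camera. The insulin-like median was 0.77 in place of 1.53 without mutant replicate 2. For the lists with no such pair of counts, those adjusted over the list alone were the same as over all genes. Neither of 2 measured ribosomal RNA genes passed.

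In all, camera called 26 lists higher and 5 lower of 54 with the preset correlation. With an estimated correlation it called 0 lists in either direction, the smallest adjusted p being 0.536, while 5 lists had an unadjusted p under 0.05. Fry, which asks only whether a list's genes move on balance in one direction, called 22 higher and 4 lower, of which 21 were lists called by camera. It did not call 10 lists that camera called: germline genes (fry adjusted p = 0.0522), epidermis markers (0.0522), globins and oxygen sensing (0.0522), nuclear hormone receptors (0.0566), vitellogenins (0.0654), oocyte and eggshell genes (0.0812), neuropeptides (0.0925), proteasome genes (0.0932), pan-neuronal markers (0.0938) and the TGF-beta list (0.0942). The 5 lists that fry alone called were metallothionein and cadmium response genes (0.00454), lysozymes (0.0337) and DAF-16 targets (0.0497) as higher, and mitochondrial unfolded protein response genes (0.0024) and MATH and BATH domain genes (0.0439) as lower.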

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

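All alternatives here were planned. In each of them 0 of the genes called both there and in the edgeR test of all libraries, 8135 calls, changed direction. At adjusted p under 0.01, 1708 genes were higher and 1162 lower, in place of 4383 and 3752. Upper quartile scaling called 2098 lower, and the test against a 1.5-fold change 1512 lower. Leaving out 1 library gave 2149 to 4659 genes higher and 1594 to 4268 lower; the fits without a control library have fewer samples, and why they lost more calls than fits without a mutant-labelled library was not tested. With an estimated correlation camera called 0 lists higher and 0 lower, and with a mean of at least 5 CPM, where 51 lists were tested, 3 lists lower; the cause was not tested. Of the 31 lists called by camera, 27 were called with RLE scaling, 29 with library sizes only, 27 with a mean of at least 5 CPM and 28 with the replicate block. DESeq2 called 8696 genes and voom with quality weights 9572. DESeq2 gave no adjusted p for several of the largest rises, among them *sqt-1* and *col-147*. Same-numbered libraries deviated from their group means with correlations of 0.193, -0.019 and -0.236 across genes, against -0.185 to 0.202 for differently numbered libraries. No pairing by number was seen, though 3 libraries per group are too few to exclude it. With the replicate block 3553 genes were higher and 3016 lower. Of the individual genes followed through each alternative, 8, 13 and 13 lost their call without control replicate 1, 2 and 3, and 3, 2 and 1 without mutant replicate 1, 2 and 3. The number was 4 with no filter on low counts, 2 with upper quartile scaling, 2 with a mean of at least 5 CPM, and 1 each with RLE scaling and with library sizes only. With the replicate block 3 did, *ilys-4*, *lys-7* and *cebp-2* (edgeR adjusted p = 0.0784, 0.0671 and 0.0856). *nsy-1*, which had not passed, had a log2 fold change of -0.053 with voom and -0.025 without mutant replicate 2, in place of 0.33, and leaving out 1 library gave -0.025 to 0.513; the cause was not tested. With the measured spread, simulated counts at these totals gave 50% of 4-fold changes and 5% of 2-fold changes. Only 100 genes were changed at each size, so the adjusted p threshold was stricter than with 8135 calls. These shares do not measure recovery in the real comparison, and the part of depth in them was not tested.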

Other observations

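Further lists of cuticle and signalling genes were counted without a test of enrichment; these lists, and every test in this part except that of transcript length, were chosen after the results had been seen. Of 52 measured hedgehog-related and patched-related genes, which act in the epidermis and its apical matrix, 44 were higher and 1 lower by the edgeR test, with a median log2 fold change of 3.62 (2.48 without mutant replicate 2). Of 26 cuticlins, structural proteins of the cuticle, 22 were higher and none lower (median 2.96, and 2.28 without mutant replicate 2). Of 15 astacin proteases 7 were higher and none lower (median 1.43, and 0.87 without mutant replicate 2). Of 25 genes of the larval and late embryonic matrix and of molting, 23 were higher and 1 lower (median 3.79), and without mutant replicate 2 the counts were also 23 and 1 (median 3.38).

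The direction of the calls differed between chromosomes (Fisher's exact test over genes, two-sided, adjusted over 6 chromosomes; genes are not independent replicates). On chromosome X 1003 genes were higher and 219 lower, 82.1% of calls against 48.8% on the other chromosomes (adjusted p = 6.18e-110). On chromosome V 951 were higher and 559 lower, 63% against 51.8% (adjusted p = 3.54e-15). Rises made up 38.1% of the calls on chromosome I, 47% on II and 40.9% on III (adjusted p = 2.48e-35, 1.1e-08 and 1.22e-23), and 52.9% on IV (adjusted p = 0.466). The median log2 fold change was 1.15 on X and 0.77 on V, and -0.43, -0.24, -0.36 and 0.09 on I, II, III and IV. No explanation of this was tested.

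The groups differed by 8135 genes, and the other 9 of the 10 splits of the 6 libraries into 3 and 3 gave at most 0 by the edgeR test, with at most 290 genes at an unadjusted p under 0.05 against 9023. Only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits put both labels on each side, which widens the spread within a side. Their low numbers therefore say little on chance.

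Reads at *odr-1*, *glb-20*, *unc-86* and C30A5.11 were high in the libraries labelled mutant, although the labels give *kyIs262* to the control. For *odr-1*, *glb-20* and C30A5.11 the lowest log2 fold change (C30A5.11 at its bound) exceeded the highest of 31 other pan-neuronal and AWC markers, 4.04 for *ceh-36*, by 3.18. Relative to those markers, a larger share of neurons alone is argued against for these genes. Neuropeptide genes were not among the markers compared. For *unc-86* a larger share of neurons stays open, since that gene exceeded the highest marker by 0.97, and by -0.01 without mutant replicate 2. *odr-1* and *glb-20* led their lists by p, and C30A5.11 was singled out after its values were seen. The gap to the other markers therefore owes something to that choice. Developing progeny as a source of these reads was not tested. If *kyIs262* holds sequences of both genes, the counts go against genotype labels as written. C30A5.11 had at least 124 counts in each mutant-labelled library and 0 in the control-labelled libraries together. These counts do not settle the labels. C30A5.11 was singled out for its values, and *osm-8* on chromosome II also had 0 control counts, against 334 mutant counts. Exchanged group labels, or *kyIs262* present in the mutant and absent from the control, cannot be told apart, because *srbc-48* had 0 reads in all 6 libraries, and an exchange of the groups would turn every direction given for the mutant.

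The collagen rise is not accounted for by scaling, as the median stayed between 5.44 and 5.94 over 4 scalings, nor by transcript length, as 0% of 10000 random lists matched on exon length reached the collagens' 5.57 (highest 1.1). Mutant-labelled animals all still at the last larval stage, when sperm are made, are argued against. The labels give growth to young adults before infection. Yolk protein genes, expressed in adults, took 19.2%, 14.4% and 23.3% of counts in mutant-labelled replicates 1, 2 and 3. They took 8.49% to 8.66% in the control-labelled libraries. A share of such larvae stays open: only 3 of 31 major sperm protein genes were high enough to test. The sum over all 31, 0.487 to 1.6 times the control mean in the mutant-labelled libraries, rests on 62 to 229 counts in each of the 6 libraries. Developing progeny in or with the adults may contribute, and this also stays open: larval and molting genes exceeded adult cuticle collagens by 2.88 (exact permutation test, two-sided, p = 0.0705), with 3 adult collagens measured. Embryonic zygotic genes, not part of that test, went both ways. Of 23, 11 fell, among them *vet-1* and *vet-2*, and 9 rose, among them *pha-4* and *ceh-22*. The labels give both groups a *fer-1* background, a gene needed for sperm function, and whether progeny were present was not tested. The genotype difference was not tested apart from these and stays open.

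The rise of immune effector genes could follow from a larger share of intestine RNA. The median log2 fold change of 17 p38 targets was -0.28 relative to that of 19 intestine markers (permutation test, two-sided, p = 0.452), so their median rise was not larger. The 17 leave out 6 pathway components, a choice made after the data were seen; with all 23 members the difference was -0.35 (permutation test, p = 0.213). A p above the threshold does not show that the lists moved alike, and an effect of the genotype on immunity was not tested apart from tissue share.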
